A study of Homo sapiens with 30 samples.

How the data were processed

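Polyadenylated RNA of human cancer cell lines was measured in 30 libraries. Per the labels' protocols, RNA was isolated from biological triplicates with an RNeasy kit, stranded libraries were made with the TruSeq mRNA kit, and paired 50-base reads were sequenced on a HiSeq with 30 M (mega) reads planned per sample. Per the labels, treatments were ML-792 at 500 nM or DMSO at 0.01%, for 16 h in HCT116 (a colorectal line), COLO205 and MDAMB231 (a breast line), and for 3.5 h in HCT116 with or without heat shock. Heat shocked cells had 2 h of treatment, 0.5 h at 43 °C and 1 h at 37 °C, per the labels' protocols. The values deposited are FPKM for each gene, in 1 table of 30373 genes by 30 libraries. The submitters' processing notes name DESeq2 1.10.1 without stating its role. The aligner, genome build and annotation are not given in the sources used here, so no coordinates are printed.

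Groups came from the cell line, treatment, time and heat shock given in the labels, 10 groups of n = 3, and all 30 columns were used. No paired analysis was possible because the labels give no replicate numbers shared between groups. The planned test was a count model, with limma as the fallback for normalized values. Since the files hold FPKM, the limma fallback was used, and the alternatives that need counts (other size factors, a Wald test on counts and voom) were not run. The design, the comparisons, the lists and the first group of alternatives given below were fixed before the data were examined.

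Gene tests used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend and robust) on log2(FPKM + 1), keeping genes at 1 FPKM or more in at least 3 libraries of the fit. This scale understates the fold changes of genes with low values. There were 3 fits with 1 mean per group: the 18 libraries of 16 h (14251 genes), the 12 HCT116 libraries of 3.5 h (12191 genes), and the 12 HCT116 libraries without heat shock of both times (12462 genes). A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the comparison, and a second count also asked for a change of at least 2-fold. ML-792 was compared with DMSO in each line at 16 h, in HCT116 at 3.5 h without heat shock and in HCT116 with heat shock. Heat shock was compared with none in DMSO and in ML-792. Differences between lines (each pair, and a joint F test), between times and between heat shock with and without ML-792 were tested as interaction contrasts. Expected overlaps of lists are the numbers for independent lists of the same sizes.

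Gene lists were tested with camera of limma at an inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Each was tested again with the correlation estimated from the data, and with fry. Camera asks whether a list changed relative to the other genes, and a rise or fall in camera is meant in that sense. Fry asks whether a list differs from no change, which is another question. A call said to be lost with fry is one whose list did not pass that other test. The 22 lists were the SUMO pathway, heat shock chaperones, immediate early genes, p53 targets, G2 and mitosis, DNA replication and S phase, interferon response, NF-kB and cytokines, cholesterol synthesis, ATF4 and amino acid response, ER unfolded protein response, NRF2 targets, hypoxia response, ribosome biogenesis, histone genes with a polyadenylated form, germline and cancer-testis genes, WNT targets, TGF-beta and BMP targets, intestinal epithelium markers, mesenchymal markers, ZNF-named genes and mitochondrially encoded genes. Some genes are in more than 1 list. Of the list symbols 1 had no match in the file. Gene names were matched to RefSeq symbols, with 21670 (71.3%) of the names in the file matched. RefSeq also served for the order of neighbours. Transcript length and GC content were those of the longest GENCODE transcript of each gene.

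Genes named in the text follow a fixed rule. In each comparison of 2 groups these are the 6 largest rises and 6 largest falls among called genes in the upper part of mean values (above the median) whose groups do not overlap, without LOC, clone or pseudogene names. In each interaction they are the 4 largest on each side. Added to them are the 3 members with the smallest adjusted p of each called list and, for ML-792, a fixed set of SUMO genes with SAE1, UBA2, SUMO2 and SUMO3 in it. Results of some genes that the rule names are withheld and not printed. Members of fixed lists named to describe those lists, and genes shared by the lines, were picked after their values were seen.

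Relative depth was the most frequent ratio to 1 reference library among genes under 0.3 FPKM in every library. The share of ratios at that value was counted with a tolerance of log2 0.03. The scale in fragments came from the most frequent steps of low values in 1414 genes with a single transcript over 1500 bases. In 4 of the 12 libraries of 3.5 h, 3 of them heat shocked, steps of double size were the most frequent, so whether a step is a fragment or a read end stays open. The summed FPKM of a library ran from 0.461 to 0.524 M at 16 h, from 0.608 to 0.732 M with heat shock and from 0.553 to 0.576 M without it at 3.5 h. In a principal component analysis PC1 held 60.5% of the variance at 16 h and 73.3% at 3.5 h, and PC2 36.5% and 11.8%.

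The tests were tried on simulated data with 50 genes changed at each size. At a log2 change of 0.5 the share recovered was 94% for HCT116 at 16 h, 90% at 3.5 h, 82% for ML-792 with heat shock and 66% for the interaction with heat shock. At a log2 change of 0.3 these shares were 76%, 50%, 46% and 18%. All changed genes that were called (100%) had the right sign. Unchanged genes made up between 3 and 14 of the calls of a comparison, for example 14 of 199 for HCT116 at 16 h, 12 of 180 for heat shock in DMSO and 5 of 145 for the interaction with heat shock. The simulated noise was independent, with 1 spread per gene in all libraries, and only genes above the median were changed. The real libraries spread more widely after heat shock and varied together with GC content within groups. These shares may therefore not hold for the data, above all with heat shock.

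Alternatives planned from the start were no filter, a filter at 5 FPKM, an adjusted p of 0.01, pseudocounts of 0.1 and 5, only the groups compared in the fit, each library left out in turn, the estimated correlation and fry. Alternatives chosen after the data were seen were median-of-ratios scaling, scaling to equal totals, array weights, removal of the trend on transcript length and GC content in each library, and leaving out HCT116 DMSO heat shock library 3 and ML-792 heat shock library 2 together. Array weights did not converge and were not used. Labels were also reassigned between libraries of the same fit and the calls counted again. Library codes of the heat shocked groups form a series of their own, so a batch of libraries and the heat shock cannot be told apart.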

Results

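Messenger RNA was sequenced from 3 human cancer cell lines exposed to ML-792 (ML00754792 in the labels), an inhibitor of the SUMO-activating enzyme, or to DMSO as vehicle. The SUMO-activating enzyme is a heterodimer of SAE1 and UBA2 that starts the attachment of small modifier proteins, SUMO2 and SUMO3 among them, to other proteins. HCT116 and COLO205 are colorectal cancer lines, and MDAMB231 is a breast cancer line. The 30 libraries formed 10 groups of 3, described by the labels as biological triplicates. In the 16 h experiment, each line received 500 nM ML-792 or vehicle for 16 h (18 libraries). In the 3.5 h experiment, HCT116 cells received ML-792 or vehicle with or without a heat shock (12 libraries). Heat shocked cells had 2 h of drug, 0.5 h at 43 °C and 1 h of recovery, all in ML-792 or vehicle.

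Gene values were FPKM (fragments scaled to transcript length and library total), as deposited. Depth was estimated from ratios of low values between libraries, with the scale set by their smallest steps. It ran from 27.6 to 35.4 M (mega) fragments in the 16 h libraries, from 37.8 to 56.2 M in the heat shocked libraries and from 48.8 to 74.3 M in the 3.5 h libraries without heat shock. The scale counts the step of most libraries as 1 fragment. In 4 libraries with double steps the step alone gave less, for example 18.9 M against 37.8 M in ML-792 heat shock library 1. Between 11535 and 12323 genes reached 1 FPKM in a library. Replicates of a group had a Pearson correlation of at least 0.991 across genes, and no pair of replicates within a group held identical values. The median SD between replicates was wider after heat shock (log2 0.0975 in DMSO and 0.117 in ML-792) than without it (0.0422 and 0.0446). In the 16 h groups it lay between 0.0484 and 0.0714. Mitochondrially encoded transcripts made up 16.3% to 18.9% of the summed FPKM at 16 h, 11.5% to 12% at 3.5 h without heat shock and 9.05% to 10.1% after heat shock. Below, changes are log2 ratios on the FPKM + 1 scale ± SE from limma, between groups of n = 3, and levels are mean FPKM ± SD (n = 3). Adjusted p-values are Benjamini-Hochberg values from limma for genes and from camera for gene lists.

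**Figure D1:**
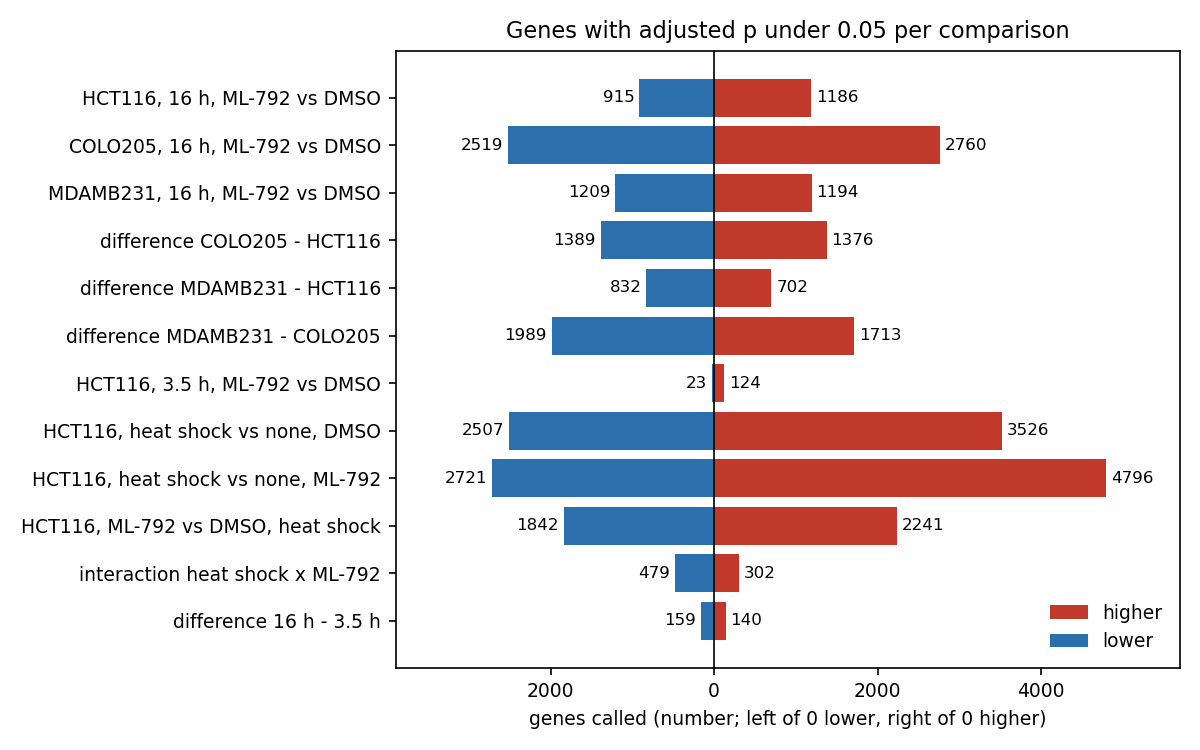
Number of genes called at an adjusted p under 0.05 (horizontal axis) in each comparison (vertical axis), with higher genes to the right of 0 and lower genes to the left. The heat shock comparisons hold the longest bars (6033 and 7517 genes in all), and the 3.5 h ML-792 comparison without heat shock the shortest (147 genes).

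The comparison of ML-792 with DMSO in HCT116 at 16 h asked which transcripts respond to this inhibitor of the SUMO-activating enzyme. Among genes with a mean above the median, to which rankings by size are limited in every comparison, the largest rise was that of DHRS2, a short-chain dehydrogenase/reductase, by 3.42 ± 0.13 from 5.65 ± 0.29 to 70.3 ± 1.8 FPKM (adjusted p = 1.9e-11). ASMTL rose by 1.97 ± 0.15, ATF7IP, a cofactor of the H3K9 methyltransferase SETDB1, by 1.5 ± 0.05, and CDKN3, a phosphatase acting on cyclin-dependent kinases, by 1.40 ± 0.05. OSGIN1, an oxidative stress gene, rose by 1.30 ± 0.09. The metalloprotease gene ADAM19 fell by 1.25 ± 0.06, the WNT antagonist DKK1 fell by 1.19 ± 0.07, the urokinase gene PLAU fell by 1.14 ± 0.05 and the integrin gene ITGB4 fell by 1.01 ± 0.06. Among the components of the SUMO pathway itself, SUMO3 rose by 1.30 ± 0.05 from 17.4 ± 0.30 to 44.3 ± 1.7 FPKM (adjusted p = 3.2e-12) and SUMO2 by 0.44 ± 0.05 from 397 ± 17 to 539 ± 33 FPKM. The enzyme subunits did not pass the test, with changes of -0.03 ± 0.03 for SAE1 (adjusted p = 0.55) and 0.04 ± 0.05 for UBA2 (adjusted p = 0.66).

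Of 30 genes of G2 and mitosis in HCT116, 21 rose and 0 fell (25 rose when adjusted over the list alone), among them the mitotic kinesin KIF20A by 0.51 ± 0.06 and cyclin B1 (CCNB1) by 0.40 ± 0.06. The list rose in camera (adjusted p = 2.08e-12, and adjusted p = 0.313 with an estimated correlation). Of 430 ZNF-named genes, most of which encode zinc finger proteins, 137 rose and 4 fell (160 and 11 adjusted over the list alone), including ZNF274 by 0.99 ± 0.07, ZNF84 by 0.76 ± 0.06 and ZNF266 by 0.66 ± 0.06. Camera gave adjusted p = 9.13e-11, and 0.0264 with an estimated correlation. Of 25 p53 targets, 7 rose and 0 fell (10 and 0 adjusted over the list alone; camera adjusted p = 0.000244, and 0.013 with an estimated correlation). They included MDM2, the ubiquitin ligase of p53, by 0.44 ± 0.06, the death receptor gene FAS by 0.30 ± 0.05 and the DNA repair gene DDB2 by 0.27 ± 0.05. The ATF4 and amino acid response list fell in camera (adjusted p = 0.0173, adjusted p = 0.649 with an estimated correlation and 0.222 with fry), with 2 of 25 members lower, also when adjusted over the list alone.

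Another 6 lists passed camera in HCT116 with adjusted p between 0.0216 and 0.0461, and between 0.446 and 0.649 with an estimated correlation. In the SUMO pathway 4 of 28 genes rose (among them SUMO3, SUMO2 and the deSUMOylating peptidase DESI2) and 4 did so adjusted over the list alone. For the heat shock chaperones these counts were 7 higher and 1 lower of 24 (8 and 1 adjusted over the list alone), led by the collagen chaperone SERPINH1 (0.70 ± 0.07) and HSPH1 (0.47 ± 0.06). Of 12 histone genes with a polyadenylated form 3 rose by either count, of 36 interferon response genes 6 rose by either count, and of 23 cholesterol synthesis genes 6 fell by either count. Of 22 ribosome biogenesis genes 2 rose and 4 fell (2 and 7 adjusted over the list alone). Each of these 6 calls was lost without at least 1 of DMSO libraries 1, 2 and 3 and ML-792 libraries 1 and 3, with adjusted p between 0.0516 and 0.133, and that of the SUMO pathway also under both other scalings (0.0508 and 0.0544). The highest adjusted p with another processing choice was 0.0597 for the histone list (pseudocount 5), 0.141 for interferon response (pseudocount 5) and 0.0882 for the SUMO pathway (trend on GC content and length removed).

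In all, limma called 2101 of 14251 genes in HCT116 at 16 h, 1186 higher and 915 lower, of which 31 changed at least 2-fold (23 higher, 8 lower). Without DMSO library 3, ML-792 library 2 or ML-792 library 3, the count was 1270, 1266 or 1180, and in a fit of this line alone 1316. The share of calls that were higher, 56.4%, became 45.3% with median-of-ratios scaling and 35.4% with equal totals.

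COLO205 cells were compared in the same way at 16 h. A neighbouring pair of genes had some of the largest rises. ENTPD8, an ectonucleotidase, rose by 5.66 ± 0.06 from 0.865 ± 0.082 to 93.1 ± 1.8 FPKM (adjusted p = 5.1e-21), and NSMF rose by 4.15 ± 0.07 from 12.5 ± 0.31 to 238 ± 3.8 FPKM. ADIRF, an adipogenesis regulator, rose by 4.16 ± 0.10, the lipid droplet protein gene PLIN2 by 2.88 ± 0.05 (82.3 ± 2.7 to 614 ± 21 FPKM), the imprinted RNA H19 by 2.81 ± 0.10 and DHRS2 by 2.37 ± 0.13. The stress-induced mTORC1 inhibitor DDIT4 fell by 1.73 ± 0.11 from 298 ± 35 to 89.7 ± 14 FPKM, the hyaluronan-binding protein gene KIAA1199 fell by 1.49 ± 0.04 and the EGFR inhibitor ERRFI1 fell by 1.42 ± 0.16. SUMO3 rose by 1.01 ± 0.05 and SUMO2 by 0.84 ± 0.05, while SAE1 changed by -0.08 ± 0.03 (adjusted p = 0.07) and UBA2 by -0.06 ± 0.05 (adjusted p = 0.42), neither passing the test.

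**Figure D2:**
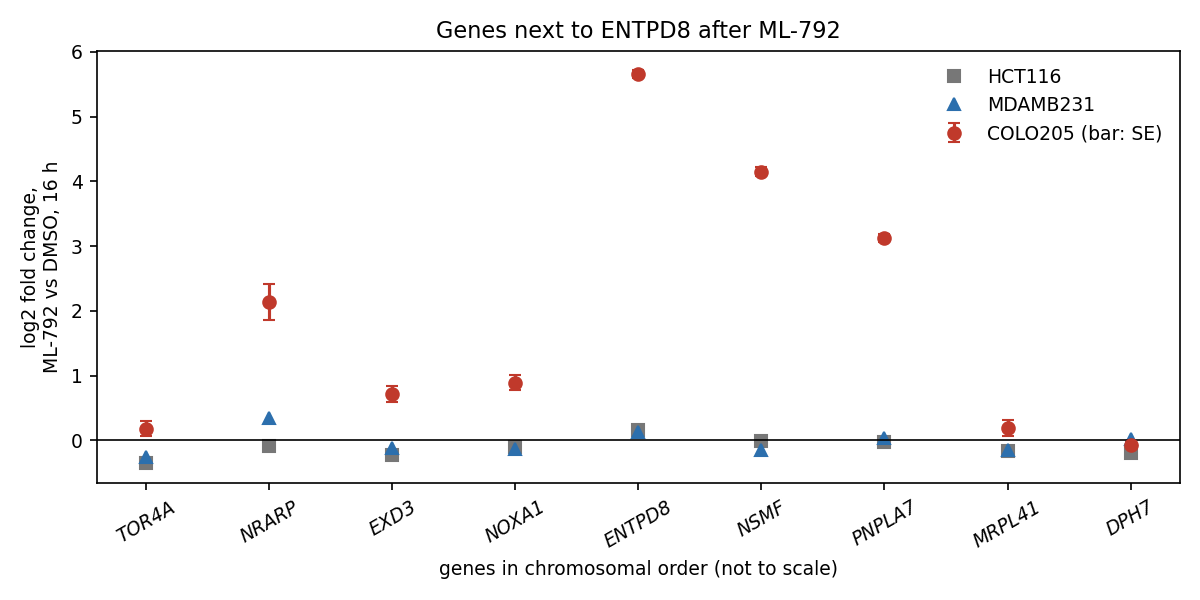
Change with ML-792 at 16 h (log2 fold change, vertical axis) of ENTPD8 and its neighbours in annotated order (horizontal axis, not to scale) in the 3 cell lines, with SE bars for COLO205. In COLO205 ENTPD8 (5.66), NSMF (4.15) and PNPLA7 (3.12) stand far above the values of HCT116 and MDAMB231.

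Of 30 genes of G2 and mitosis, 29 rose in COLO205, also when adjusted over the list alone, with KIF20A at 0.67 ± 0.06 and PRC1 at 0.50 ± 0.04 (camera adjusted p = 4.23e-13, and adjusted p = 0.206 with an estimated correlation). Ribosome biogenesis genes fell, 20 of 22 (21 adjusted over the list alone), among them the pseudouridine synthase DKC1 by a change of -0.48 ± 0.04 and the methyltransferase fibrillarin (FBL) by -0.38 ± 0.03. Camera gave adjusted p = 2.05e-12, and 0.0418 with an estimated correlation. Of 25 ATF4 and amino acid response genes, 19 fell by either count, including the glycyl-tRNA synthetase GARS and the serine hydroxymethyltransferase SHMT2, both at -0.41 ± 0.04. The list fell in camera (adjusted p = 1.41e-09, and adjusted p = 0.206 with an estimated correlation). In contrast, 13 of 16 genes of the ER unfolded protein response rose (14 adjusted over the list alone), such as the ER chaperones HSPA5 at 0.62 ± 0.05 and HSP90B1 at 0.69 ± 0.05. This list rose in camera (adjusted p = 2.24e-09, and adjusted p = 0.188 with an estimated correlation).

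DNA replication and S phase genes were higher in 14 and lower in 1 of 32 (16 and 1 adjusted over the list alone), led by the histone mRNA stem-loop binding protein SLBP at 1.05 ± 0.05. Camera called the list higher (adjusted p = 0.00234, and adjusted p = 0.581 with an estimated correlation). Of 36 interferon response genes, 15 rose and 4 fell by either count. OAS1 rose by 1.72 ± 0.07, whereas its relative OASL fell by 0.86 ± 0.04 (camera adjusted p = 0.0154, and adjusted p = 0.206 with an estimated correlation). Cholesterol synthesis genes rose in 11 and fell in 2 of 23 by either count, with INSIG1 at 0.81 ± 0.06 (camera adjusted p = 0.0166, and adjusted p = 0.374 with an estimated correlation). ZNF-named genes rose in 127 and fell in 39 of 430 (128 and 41 adjusted over the list alone), with ZNF165 at 1.15 ± 0.07 (camera adjusted p = 0.0102, and adjusted p = 0.374 with an estimated correlation). With the trend on GC content and length removed, camera gave 0.129 for this list, and with a filter at 5 FPKM 0.153. In a fit of COLO205 alone the interferon list gave 0.0573. Of 5 germline and cancer-testis genes, 2 rose by either count, with no call in camera (adjusted p = 0.0751).

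Immediate early genes were lower in 9 and higher in 1 of 25 in COLO205, and genes of NF-kB and cytokines were lower in 6 and higher in 0 of 20, all by either count. MYC, the transcription factor, fell by 0.74 ± 0.07 and the cytokine gene LIF fell by 0.99 ± 0.05 (camera adjusted p = 0.00389 and 0.00534, and adjusted p = 0.581 and 0.527 with an estimated correlation). Mitochondrially encoded genes were higher in 8 of 18 (9 adjusted over the list alone; camera adjusted p = 0.0197, and adjusted p = 0.616 with an estimated correlation). Without ML-792 library 3 all 3 of these calls were lost (adjusted p = 0.0816, 0.0816 and 0.119), and the mitochondrial one also without DMSO library 2 (0.0547), with the trend on GC content and length removed (0.0938) and with no filter (0.171). limma called 5279 genes, 2760 higher and 2519 lower, with 115 at 2-fold or more (82 higher, 33 lower). With equal totals the balance turned to 2466 higher and 2697 lower.

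In MDAMB231 cells ML-792 was compared with DMSO at 16 h. GDF15, a stress-induced member of the TGF-beta family, rose by 2.60 ± 0.25 from 4.47 ± 0.71 to 32.1 ± 4.9 FPKM (adjusted p = 5.8e-06). The cytokine gene IL11 rose by 2.51 ± 0.07 from 4.28 ± 0.11 to 29.2 ± 3.8 FPKM, and TNFAIP2, a TNF-induced gene, by 2.25 ± 0.06 from 58.5 ± 1.5 to 281 ± 12 FPKM. G0S2, an inhibitor of triglyceride lipase, fell by 1.42 ± 0.15, the tissue plasminogen activator gene PLAT fell by 1.35 ± 0.06, the EGFR-family ligand NRG1 fell by 1.17 ± 0.07 and the hexokinase gene HK2 fell by 0.80 ± 0.04. SUMO3 rose by 0.23 ± 0.05 from 101 ± 1.7 to 119 ± 2.3 FPKM (adjusted p = 0.0021). SAE1 and UBA2 did not pass the test (-0.01 ± 0.03 and -0.08 ± 0.05, adjusted p = 0.91 and 0.34).

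Of 15 TGF-beta and BMP targets in MDAMB231, 9 rose and 0 fell (12 and 0 adjusted over the list alone). They included ID3, an inhibitor of bHLH factors, by 1.30 ± 0.08 and the matrix protein gene TGFBI by 0.55 ± 0.04 (camera adjusted p = 5.93e-09, and 0.0101 with an estimated correlation). Cholesterol synthesis genes rose in 13 of 23 (15 adjusted over the list alone), with the HMG-CoA synthase HMGCS1 at 1.37 ± 0.15 and the sterol oxidase MSMO1 at 0.68 ± 0.06. Their list rose in camera (adjusted p = 1.24e-08, and 0.0185 with an estimated correlation). Hypoxia response genes fell in 11 of 17 by either count, such as carbonic anhydrase CA9 by a change of -0.69 ± 0.06 and enolase ENO2 by -0.52 ± 0.04. That list fell (camera adjusted p = 2.7e-07, and 0.0101 with an estimated correlation). The single member of that list that rose was ANGPTL4 (0.91 ± 0.08), a lipoprotein lipase inhibitor that also responds to lipid-sensing receptors. Interferon response genes rose in 14 and fell in 1 of 36 (16 and 1 adjusted over the list alone), led by SAMD9L at 0.61 ± 0.05 (camera adjusted p = 2.34e-06, and 0.0101 with an estimated correlation).

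In MDAMB231 16 of 32 DNA replication and S phase genes were lower and 0 higher (19 and 1 adjusted over the list alone). The helicase subunits MCM5 and MCM6 changed by -0.43 ± 0.06 and -0.37 ± 0.05 (camera adjusted p = 1.38e-06, and adjusted p = 0.346 with an estimated correlation). Histone genes with a polyadenylated form rose in 7 of 12 (9 adjusted over the list alone), with HIST1H2BK at 0.63 ± 0.04 (camera adjusted p = 2.86e-06, and adjusted p = 0.121 with an estimated correlation). Of 20 genes of NF-kB and cytokines, 7 rose and 2 fell (8 and 2 adjusted over the list alone), with IL6 at 1.02 ± 0.05 (camera adjusted p = 9.36e-06, and adjusted p = 0.237 with an estimated correlation). ZNF-named genes rose in 67 and fell in 12 of 430 (72 and 13 adjusted over the list alone). ZNF841 changed by 0.99 ± 0.05 and ZNF175 by -0.72 ± 0.06 (camera adjusted p = 4.75e-05, and adjusted p = 0.121 with an estimated correlation). The G2 and mitosis list fell in camera (adjusted p = 0.0301, and adjusted p = 0.725 with an estimated correlation) with 2 of 30 genes lower and 0 adjusted over the list alone, a call lost without DMSO library 1 (0.0973) or ML-792 library 1 (0.166) and with fry (0.272). limma called 2403 genes in this line, 1194 higher and 1209 lower, with 37 at 2-fold or more (33 higher, 4 lower). The balance was 1275 higher and 1186 lower with median-of-ratios scaling and 1034 and 1389 with equal totals.

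**Figure D3:**
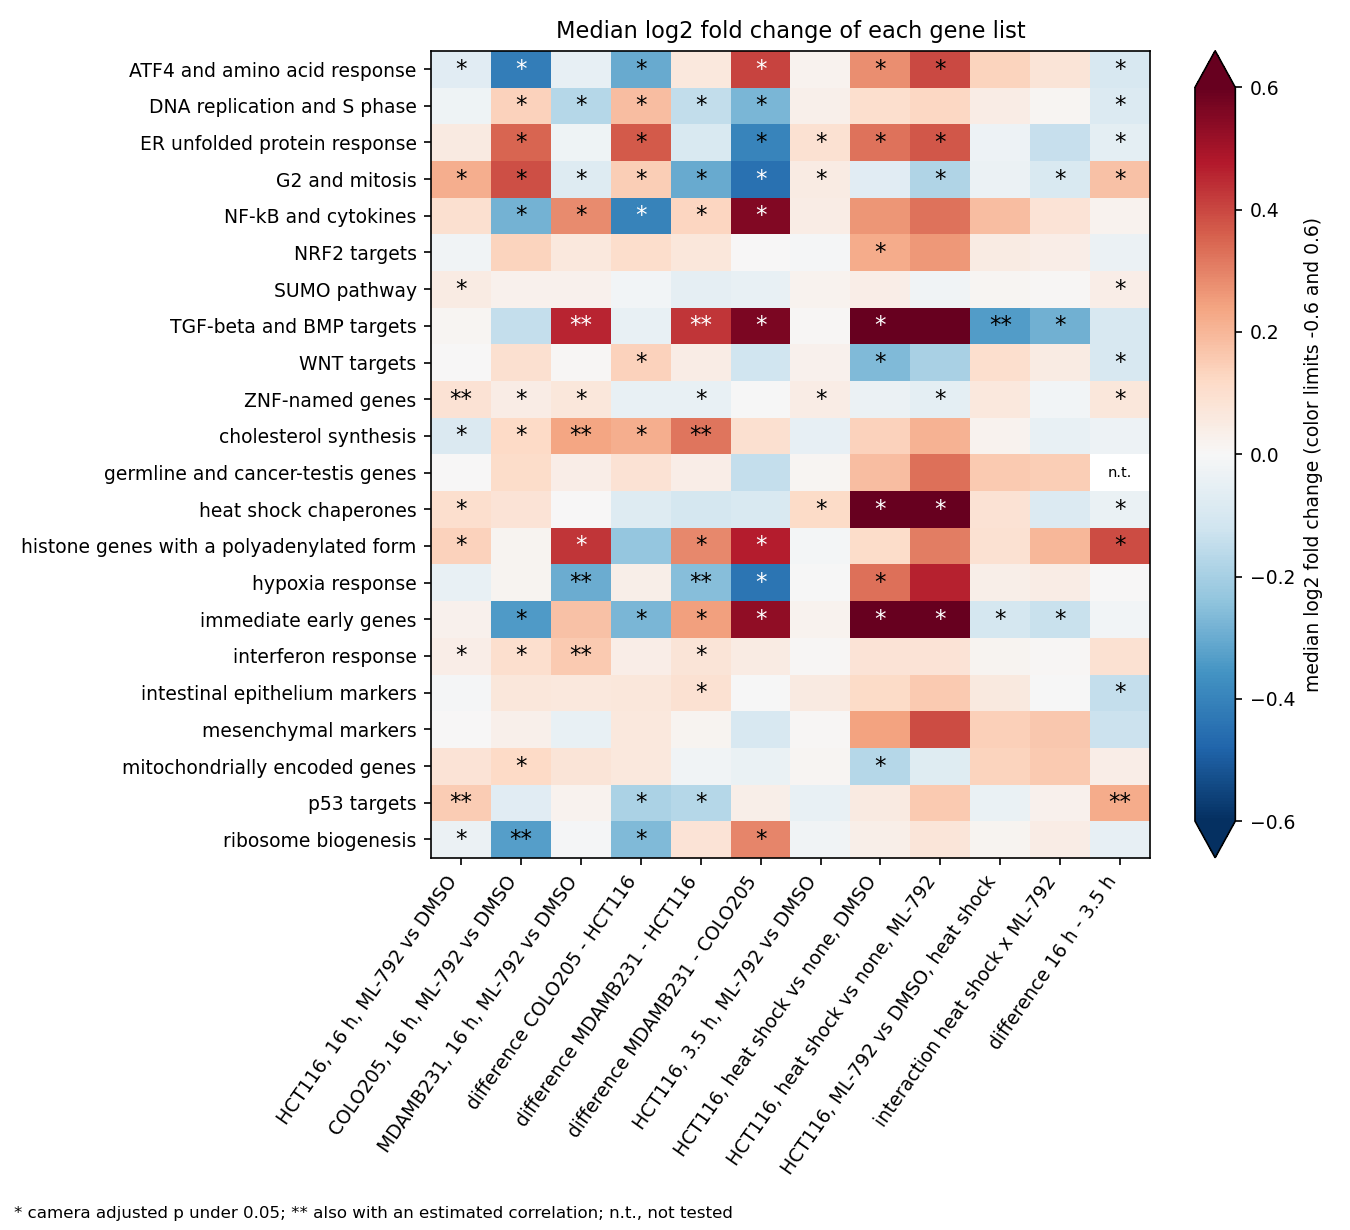
Median log2 fold change of each fixed gene list (vertical axis) in each comparison (horizontal axis), as a colour scale with capped ends, with 1 asterisk where camera called the list and 2 where it also did with an estimated correlation. G2 and mitosis genes are above 0 in HCT116 and COLO205 (21 and 29 of 30 genes higher), and the chaperone list has its largest medians after heat shock.

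Which part of the 16 h response was common to the lines was asked by intersecting the calls. In all 3 lines 175 genes were higher, against 19.2 for independent lists, and 117 were lower, against 13.7. With equal totals the balance turned to 122 higher and 184 lower, and with the trend on GC content and length removed the numbers were 271 and 203. When each line was fitted alone, 115 were higher and 87 lower. Among them, chosen after their values were seen, were the zinc finger gene ZSCAN31 (1.81, 1.92 and 1.26 in HCT116, COLO205 and MDAMB231), CDKN3 (1.40, 1.27 and 0.87), DHRS2 (3.42, 2.37 and 0.78) and ATF7IP (1.5, 1.09 and 0.38). Among the lower genes were PLAU (-1.14, -0.68 and -0.53), ERRFI1 (-0.63, -1.42 and -0.55), ADAM19 (-1.25, -1.52 and -0.39) and the AP-1 subunit FOSL2 (-0.71, -0.88 and -0.58). Across genes, which are not independent replicates, the changes had a Pearson correlation of 0.34 between HCT116 and COLO205, 0.29 between HCT116 and MDAMB231 and 0.21 between COLO205 and MDAMB231. Genes called in opposite directions numbered 130, 75 and 250 in these pairs. The changes in HCT116 and COLO205 both had a negative Spearman correlation with GC content (-0.46 and -0.26), unlike MDAMB231 (0.01). The correlations between lines were not computed with that trend removed, so a part of them may come from it.

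Differences between lines were tested directly as interaction terms. The COLO205 effect exceeded the HCT116 effect by 5.50 ± 0.08 for ENTPD8, 4.16 ± 0.10 for NSMF, 4.13 ± 0.14 for ADIRF and 3.01 ± 0.06 for PLIN2. In HCT116 these genes stood at similar levels with and without drug, for example ADIRF at 162 ± 6.4 and 159 ± 17 FPKM. The difference was negative for the EGFR ligand EREG (-1.52 ± 0.34), ASMTL (-1.43 ± 0.21), the trypsinogen gene PRSS1 (-1.36 ± 0.28), which was listed at 0 in all HCT116 libraries, and the polyamine enzyme ODC1 (-1.34 ± 0.13). By list, the COLO205 effect was lower for 16 of 22 ribosome biogenesis genes (17 adjusted over the list alone) and 15 of 25 ATF4 and amino acid response genes (15 lower and 2 higher adjusted over the list alone). It was higher for 13 and lower for 1 of 16 ER unfolded protein response genes (15 and 1 adjusted over the list alone). Camera gave adjusted p = 4.19e-09, 3.63e-06 and 1.08e-08, and adjusted p = 0.0957, 0.388 and 0.105 with an estimated correlation. The effect on p53 targets was lower in COLO205 (6 lower and 1 higher of 25, or 9 and 1 adjusted over the list alone; camera adjusted p = 0.0136, and adjusted p = 0.0957 with an estimated correlation), with FAS at -0.37 ± 0.08. limma called 2765 differences between these lines, 1376 higher and 1389 lower, against 1532 and 1175 with median-of-ratios scaling and 1475 and 1069 with equal totals.

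Camera also called cholesterol synthesis, S phase, G2 and mitosis, NF-kB, immediate early and WNT lists between COLO205 and HCT116, with adjusted p from 2.21e-05 to 0.0298 and from 0.105 to 0.515 with an estimated correlation. In WNT targets 6 of 13 genes had a higher effect in COLO205 and 3 a lower one, by either count. DKK1, whose difference was 1.29 ± 0.09, stood near 0 in COLO205 (0.0293 ± 0.019 FPKM in DMSO) and fell in HCT116. The WNT call was lost without COLO205 ML-792 library 3 (0.0736), HCT116 DMSO library 3 (0.0505) or HCT116 ML-792 library 3 (0.0519). It was also lost with the trend on GC content and length removed (0.0765), in a fit of the 2 lines alone (0.0563) and with pseudocount 0.1 (0.127). The immediate early call was lost without COLO205 ML-792 library 3 (0.105) and with fry (0.155), and that of G2 and mitosis with fry (0.0744).

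Against HCT116, the MDAMB231 effect was higher for IL11 (2.52 ± 0.10), TNFAIP2 (1.94 ± 0.08), GDF15 (1.89 ± 0.36) and ID3 (1.87 ± 0.11). ID3 went from 60.9 ± 5.0 to 40.8 ± 4.4 FPKM in HCT116 and from 7.13 ± 0.47 to 19.1 ± 1.6 FPKM in MDAMB231. It was lower for DHRS2 (-2.64 ± 0.18), G0S2 (-1.42 ± 0.21, listed at 0 in HCT116), PLAT (-1.36 ± 0.08) and ASMTL (-1.26 ± 0.21). G2 and mitosis genes had a lower effect in MDAMB231 for 19 of 30 (25 adjusted over the list alone), with KIF20A at -0.58 ± 0.08 (camera adjusted p = 2.54e-13, and adjusted p = 0.155 with an estimated correlation). Cholesterol synthesis genes had a higher effect for 12 of 23 (18 adjusted over the list alone), with MSMO1 at 0.67 ± 0.09 (camera adjusted p = 1.46e-12, and 0.018 with an estimated correlation). TGF-beta and BMP targets were higher for 10 of 15 (11 higher and 1 lower adjusted over the list alone), with ID1 at 1.32 ± 0.18 (camera adjusted p = 3.11e-08, and 0.0233 with an estimated correlation). Hypoxia response genes were lower for 8 and higher for 1 of 17 (11 and 1 adjusted over the list alone), with the prolyl hydroxylase subunit P4HA1 at -0.63 ± 0.08 (camera adjusted p = 1.25e-05, and 0.0233 with an estimated correlation). Intestinal epithelium markers were higher for 5 and lower for 2 of 21 by either count (camera adjusted p = 0.0208, and adjusted p = 0.273 with an estimated correlation), a call lost without HCT116 DMSO library 3 (0.0511), with the trend on GC content and length removed (0.0785) and with pseudocount 5 (0.188). NF-kB, S phase and interferon lists were also called (adjusted p from 0.000209 to 0.0184, and from 0.155 to 0.479 with an estimated correlation), with IL6 at 1.02 ± 0.08 and RRM2 at -0.85 ± 0.06. The interferon call was lost with pseudocount 0.1 (0.233) and that of S phase with fry (0.0602).

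The lists of ZNF-named genes, p53 targets, immediate early genes and histone genes with a polyadenylated form passed camera between MDAMB231 and HCT116 with adjusted p from 0.0256 to 0.0393, and from 0.132 to 0.57 with an estimated correlation. ZNF-named genes had a lower effect in MDAMB231 for 56 and a higher one for 15 of 430 (64 and 22 adjusted over the list alone), with ZNF175 at -0.81 ± 0.09 and ZNF841 at 0.92 ± 0.07. The p53 target MDM2 differed by -0.40 ± 0.09 and the immediate early gene NR4A2 by 1.1 ± 0.11, and of 12 histone genes 0 were called by either count. With the trend on GC content and length removed, the calls of ZNF-named, immediate early and histone genes were lost (0.298, 0.107 and 0.0706). Among other processing choices the highest adjusted p was 0.111 for ZNF-named genes (pseudocount 5), 0.0559 for immediate early genes (median-of-ratios scaling), and 0.109 and 0.0693 for histone genes and p53 targets (pseudocount 0.1). Fry gave 0.274 for immediate early and 0.116 for histone genes. Leaving out HCT116 DMSO library 3 ended all 4 calls (0.0906, 0.0511, 0.0707 and 0.0511 in the order given). Those of ZNF-named, immediate early and histone genes were also lost without MDAMB231 ML-792 library 1 (0.148, 0.0615 and 0.0578). HCT116 DMSO library 2 or ML-792 library 1 ended those of ZNF-named genes (0.0516 and 0.0505) and p53 targets (0.0516 and 0.0505), and HCT116 DMSO library 1 those of p53 targets and immediate early genes (0.0519 for both). MDAMB231 DMSO libraries 2 and 3 ended that of p53 targets (0.0518 and 0.0616), and MDAMB231 ML-792 library 2 those of p53 targets and histone genes (0.0521 for both). limma called 1534 differences between these lines, 702 higher and 832 lower. The balance turned to 822 higher and 711 lower with median-of-ratios scaling and to 780 and 659 with equal totals.

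Between MDAMB231 and COLO205 the effects differed most, among genes with a mean above the median, for ENTPD8 (-5.54 ± 0.08), NSMF (-4.30 ± 0.10), ADIRF (-4.10 ± 0.14) and H19 (-2.83 ± 0.14) on the lower side. On the higher side were GDF15 (2.91 ± 0.36), the glucose-sensing transcription factor gene MLXIPL (2.42 ± 0.08), TNFAIP2 (2.28 ± 0.08) and the EGFR ligand AREG (1.92 ± 0.47). The effect was lower in MDAMB231 for 28 of 30 G2 and mitosis genes by either count and for 22 of 32 S phase genes (25 adjusted over the list alone), and higher for 17 of 22 ribosome biogenesis genes (20 adjusted over the list alone). Camera gave adjusted p = 1.26e-14, 3.9e-10 and 1.67e-10, and adjusted p = 0.109, 0.174 and 0.0553 with an estimated correlation. It was higher for 12 of 20 NF-kB and cytokine genes by either count (camera adjusted p = 1.05e-09, and adjusted p = 0.104 with an estimated correlation), where IL6 was listed at 0 in all COLO205 libraries. Camera also called ATF4, TGF-beta and BMP, immediate early and histone lists higher in MDAMB231 and the ER unfolded protein response and hypoxia lists lower (adjusted p from 1.72e-08 to 0.000747, and from 0.0553 to 0.332 with an estimated correlation). Differences in these lists included TGFBI at 1.63 ± 0.06, PHGDH, a serine synthesis gene, at 0.77 ± 0.09 and HSPA5 at -0.64 ± 0.07. limma called 3702 differences, 1713 higher and 1989 lower, and 4423 genes differed between the lines in a joint test of all 3.

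In HCT116 at 3.5 h without heat shock, the same comparison of ML-792 with DMSO addressed the early response. The growth factor genes GDF15 and FGF19 both rose by 1.04, with SE of 0.11 and 0.07, GDF15 from 20.4 ± 1.8 to 42.8 ± 0.50 FPKM (adjusted p = 0.00029). The focal adhesion gene TNS4 rose by 0.89 ± 0.08, CDKN3 by 0.88 ± 0.08, ATF7IP by 0.79 ± 0.13 and ID2 by 0.72 ± 0.07. ID3 and PLAU fell by 0.65, with SE of 0.09 and 0.06, ERRFI1 fell by 0.63 ± 0.06 and the heme oxygenase gene HMOX1 fell by 0.53 ± 0.07. SUMO3 rose by 0.38 ± 0.07 (adjusted p = 0.013), a call lost without DMSO library 1 or 2 or ML-792 library 1 or 2 (highest adjusted p = 0.0922), and SUMO2 did not pass the test (0.19 ± 0.07, adjusted p = 0.46).

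Of 27 heat shock chaperones 3 rose at 3.5 h (4 adjusted over the list alone), among them SERPINH1 by 0.70 ± 0.09 from 68.7 ± 0.75 to 112 ± 1.0 FPKM and HSPH1 by 0.51 ± 0.08. Camera called the list (adjusted p = 2.92e-10, and adjusted p = 0.298 with an estimated correlation). Of 334 ZNF-named genes 23 rose and 0 fell (35 and 0 adjusted over the list alone), including ZNF274 by 0.71 ± 0.09 (camera adjusted p = 6.97e-08, and adjusted p = 0.298 with an estimated correlation). The ER unfolded protein response list rose in camera (adjusted p = 5.23e-06, and adjusted p = 0.298 with an estimated correlation), with 1 of 16 genes called and 6 adjusted over the list alone. In the G2 and mitosis list 0 of 30 genes were called by either count, and its call in camera (adjusted p = 0.0147, and adjusted p = 0.557 with an estimated correlation) was lost without DMSO library 1 (0.0621) or ML-792 library 2 (0.118). In fry, which tests a list against no change and not against other genes, all 4 lists called at 3.5 h failed to pass (adjusted p = 0.0719 for chaperones, ZNF-named genes and the ER list, and 0.328 for G2 and mitosis). limma called 147 of 12191 genes, 124 higher and 23 lower, with 4 at 2-fold or more, all higher, and 894 at an unadjusted p under 0.05. Without DMSO library 1, 2 or 3 the count was 91, 91 or 93, and without ML-792 library 1, 2 or 3 it was 83, 91 or 90. A fit of these 6 libraries alone called 728 genes, and 260 were called with the trend on GC content and length removed. The fit of all 12 libraries also takes its spread from the heat shocked groups, where replicates differed more. Their median SD was log2 0.0975 in DMSO and 0.117 in ML-792, against 0.0422 and 0.0446 without heat shock. The count of 147, and tests at 3.5 h that did not pass, those of fry among them, may therefore understate the early response. Of the 123 higher genes tested in both fits, 94 were also higher at 16 h in HCT116 (11.1 for independent lists), and of 23 lower genes 18 were also lower (1.65 for independent lists).

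How the effect at 16 h differed from that at 3.5 h in HCT116 was tested as a difference of effects, each measured within its own experiment. A shift common to ML-792 and DMSO of an experiment cancels, but time and experiment cannot be told apart in this difference. The effect was larger at 16 h for DHRS2 (2.11 ± 0.09), ASMTL (1.5 ± 0.09), SUMO3 (0.92 ± 0.07) and ODC1 (0.91 ± 0.06). It was lower at 16 h for ITGB4 (-0.99 ± 0.10), the carboxypeptidase gene CPA4 (-0.95 ± 0.14), ADAM19 (-0.92 ± 0.08) and the hyaluronan synthase gene HAS3 (-0.80 ± 0.07). Of 25 p53 targets, 7 had a higher effect at 16 h (15 adjusted over the list alone), including the cyclin-dependent kinase inhibitor CDKN1A at 0.30 ± 0.05 (camera adjusted p = 3.7e-08, and 0.0065 with an estimated correlation). Of 30 G2 and mitosis genes, 6 had a higher effect (18 adjusted over the list alone; camera adjusted p = 1.81e-12, and adjusted p = 0.173 with an estimated correlation). In the S phase list RRM2, a ribonucleotide reductase subunit, had a higher effect (0.87 ± 0.06) and cyclin E1 (CCNE1) a lower one (-0.39 ± 0.05), while camera called the list lower (adjusted p = 0.00126, and adjusted p = 0.182 with an estimated correlation). Chaperones had a lower effect at 16 h, with 2 of 24 called and 5 adjusted over the list alone (camera adjusted p = 0.00573, and adjusted p = 0.258 with an estimated correlation).

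Camera called ATF4, WNT, intestinal and ER lists lower at 16 h and ZNF-named, histone and SUMO pathway lists higher, with adjusted p from 3.54e-05 to 0.0443, and from 0.106 to 0.415 with an estimated correlation. The ATF4 target CHAC1, a glutathione-degrading enzyme, differed by -0.82 ± 0.12, the WNT antagonist DKK1 by -0.74 ± 0.05 and the linker histone HIST1H1C by 0.54 ± 0.09. The SUMO pathway call, with SUMO3 the single gene called of 28 (3 adjusted over the list alone), was lost without 6 libraries (DMSO 2 and 3 and ML-792 3 of 16 h, DMSO 1 and 2 and ML-792 1 of 3.5 h; adjusted p from 0.0524 to 0.073). The ER call was lost without DMSO 1 or ML-792 1 of 16 h, or DMSO 1 or ML-792 3 of 3.5 h (adjusted p from 0.0577 to 0.131). The intestinal call was lost without DMSO 3 of 16 h (0.106), with the trend on GC content and length removed (0.0641) and with fry (0.191), and that of the SUMO pathway also with pseudocount 5 (0.0537) and a filter at 5 FPKM (0.0527).

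limma called 299 differences between the times, 140 higher and 159 lower, with 6 at 2-fold or more, all higher. With the trend on GC content and length removed it called 781, and the differences had a Spearman correlation of -0.43 with GC content across genes, which are not independent replicates. The count was 614 and 175 without 16 h DMSO libraries 1 and 2, 808, 156 and 185 without 16 h ML-792 libraries 1, 2 and 3, and 186, 160 and 169 without 3.5 h DMSO libraries 1, 2 and 3. Without 3.5 h ML-792 libraries 1 and 3 it was 180 and 159. The share of these calls that were higher, 46.8%, became 35.4% with equal totals.

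Heat shock was compared with no heat shock in DMSO to measure the heat response of HCT116. HSPA6, a strictly heat-inducible HSP70, rose by 6.01 ± 0.11 from near 0 to 64.5 ± 11 FPKM (adjusted p = 8.4e-13). The stress-induced zinc finger gene ZFAND2A rose by 4.66 ± 0.07 from 15.3 ± 0.42 to 413 ± 31 FPKM and the HSP40 gene DNAJB1 by 4.38 ± 0.08. HSPA1A and HSPA1B rose by 4.90 ± 0.66 and 4.57 ± 0.11, but these near-identical copies can exchange reads, so their separate values are uncertain. The transcriptional repressor TGIF1 fell by 2.02 ± 0.10 from 68.4 ± 2.0 to 16.1 ± 0.48 FPKM, PHLDA1 fell by 1.75 ± 0.13 and the developmental transcription factor gene SOX4 fell by 1.69 ± 0.05. All 27 heat shock chaperones rose, by either count, with the HSP70 cochaperone BAG3 at 3.74 ± 0.08 (camera adjusted p = 6.41e-23, and adjusted p = 0.139 with an estimated correlation). The list made up 2.15% ± 0.03 of the summed FPKM without heat shock and 5.71% ± 0.10 with it (SD, n = 3).

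Immediate early genes rose in 22 and fell in 1 of 28 after heat shock in DMSO by either count, with the transcription factor gene EGR3 at 3.40 ± 0.07 and IER5 at 2.91 ± 0.09 (camera adjusted p = 1.33e-13, and adjusted p = 0.233 with an estimated correlation). Of 23 ATF4 and amino acid response genes 19 rose (19, with 1 lower, adjusted over the list alone), such as DDIT3 at 2.07 ± 0.13, and of 16 ER unfolded protein response genes 14 rose by either count, with HERPUD1 at 2.22 ± 0.10. Camera gave adjusted p = 5.37e-05 and 7.65e-05, and adjusted p = 0.5 and 0.233 with an estimated correlation. TGF-beta and BMP targets rose in 8 and fell in 3 of 11 by either count, with the transcriptional repressor BHLHE40 at 2.13 ± 0.05 (camera adjusted p = 0.00589, and adjusted p = 0.233 with an estimated correlation). WNT targets fell in 6 and rose in 2 of 9 by either count (camera adjusted p = 0.0191, and adjusted p = 0.369 with an estimated correlation). Those that fell included MYC by a change of -0.85 ± 0.06 and 2 genes known as WNT antagonists, RNF43 (-0.70 ± 0.07) and DKK1 (-0.57 ± 0.08). Mesenchymal markers rose in 7 and fell in 2 of 12 by either count with no call in camera (adjusted p = 0.172). NRF2 targets and hypoxia response genes each rose in 9 of 15 by either count (0 NRF2 targets fell, or 1 adjusted over the list alone, and 2 hypoxia genes fell). HMOX1 was at 1.85 ± 0.07 (camera adjusted p = 0.0453 for both lists, and adjusted p = 0.5 for both with an estimated correlation). With equal totals the median of the NRF2 list turned from 0.22 to -0.02. Both calls were lost without DMSO heat shock library 3 (0.0633) and that of NRF2 also without library 2 (0.0629). With a filter at 5 FPKM the adjusted p was 0.254 for hypoxia and 0.0751 for NRF2, and with equal totals 0.102 for NRF2. Mitochondrially encoded genes fell in 6 and rose in 1 of 21 by either count (camera adjusted p = 0.0348, and adjusted p = 0.5 with an estimated correlation), a call lost without DMSO heat shock library 1 (0.0648) and with a filter at 5 FPKM (0.146).

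limma called 6033 genes after heat shock in DMSO, 3526 higher and 2507 lower, with 380 at 2-fold or more (337 higher, 43 lower). With equal totals the median change of all genes moved from 0.05 to -0.16 and the share of calls that were higher from 58.4% to 22.2%. The heat shocked libraries and those without heat shock carry different series of library codes, so a library batch and the heat shock cannot be told apart.

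**Figure D4:**
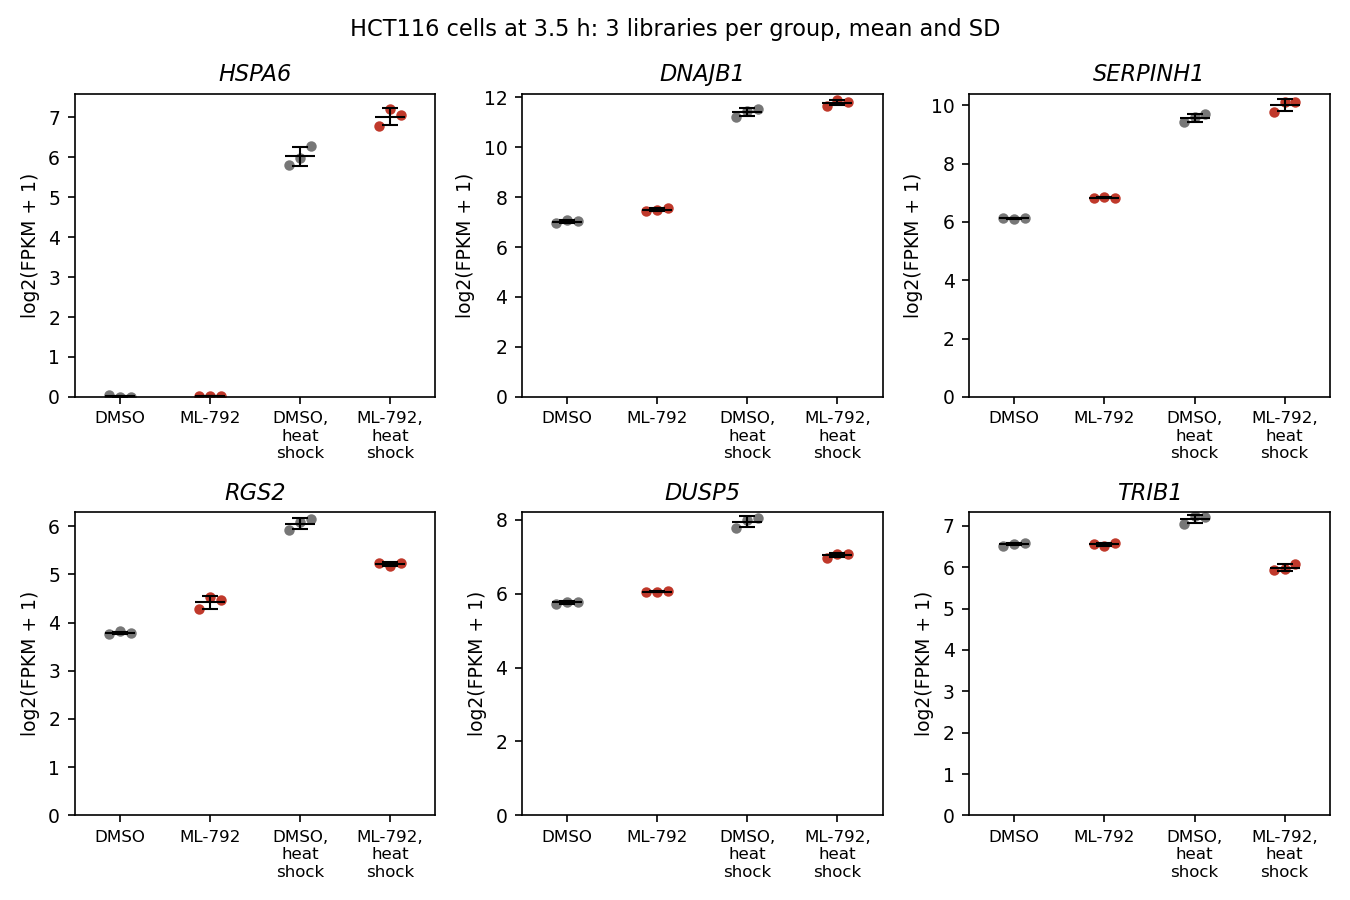
Values of 6 genes in the 12 HCT116 libraries of the 3.5 h experiment, as log2(FPKM + 1) on the vertical axis, for DMSO and ML-792 with and without heat shock (horizontal axis), with points for libraries and bars for mean and SD (n = 3). HSPA6 is near 0 without heat shock and higher with ML-792 than with DMSO after it, while RGS2, DUSP5 and TRIB1 are lower with ML-792 than with DMSO after it.

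The heat response under ML-792 was compared in the same way. HSPA6 rose by 6.99 ± 0.11 to 130 ± 19 FPKM (adjusted p = 1.9e-13), ZFAND2A by 4.36 ± 0.07, DNAJB1 by 4.29 ± 0.08, and HSPA1A and HSPA1B, uncertain as above, by 5.79 ± 0.66 and 4.93 ± 0.11. The transcription factor gene SOX9 fell by 2.15 ± 0.06 from 32.3 ± 0.18 to 6.50 ± 0.48 FPKM, the pyrimidine synthesis gene UMPS fell by 2.09 ± 0.14 and TGIF1 fell by 1.96 ± 0.10. All 27 chaperones rose by either count (camera adjusted p = 1.13e-17, and adjusted p = 0.271 with an estimated correlation), from 2.31% ± 0.01 to 6.05% ± 0.16 of the summed FPKM (SD, n = 3). Immediate early genes rose in 23 and fell in 3 of 28 by either count, with the AP-1 gene JUN at 3.99 ± 0.12 (camera adjusted p = 1.64e-08, and adjusted p = 0.468 with an estimated correlation). G2 and mitosis genes fell in 15 and rose in 6 of 30 (16 and 7 adjusted over the list alone), with cyclin A2 (CCNA2) at -0.88 ± 0.07 (camera adjusted p = 0.00448, and adjusted p = 0.468 with an estimated correlation). ZNF-named genes fell in 118 and rose in 87 of 334 by either count, and those with the smallest p rose, such as ZNF761 by 1.96 ± 0.07 (camera adjusted p = 0.00448, and adjusted p = 0.468 with an estimated correlation). That call was lost with equal totals (0.0606), with the trend on GC content and length removed (0.171), with a filter at 5 FPKM (0.388) and with fry (0.0819). ATF4 and ER unfolded protein response genes rose in 18 of 23 (1 fell) and 12 of 16 by either count, with SESN2 at 1.71 ± 0.10 (camera adjusted p = 0.000457 and 0.00616, and adjusted p = 0.468 for both with an estimated correlation).

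limma called 7517 genes after heat shock under ML-792, 4796 higher and 2721 lower, with 451 at 2-fold or more (330 higher, 121 lower). Of all calls 63.8% were higher, 50.3% with median-of-ratios scaling and 24.2% with equal totals, where the median of all genes moved from 0.10 to -0.16. Of the calls made in DMSO, 2826 higher and 1649 lower genes were called in the same direction under ML-792 (1387 and 560 for independent lists), and the changes had a Pearson correlation of 0.84 across genes, which are not independent replicates.

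The comparison of ML-792 with DMSO among heat shocked HCT116 cells asked what the inhibitor changed in cells under heat stress. HSPA6 was higher by 1.00 ± 0.11, at 130 ± 19 against 64.5 ± 11 FPKM (adjusted p = 0.00039), TNS4 by 1.02 ± 0.08 and the ubiquitin-conjugating enzyme gene UBE2B by 0.78 ± 0.08. TRIB1, a pseudokinase gene, fell by 1.17 ± 0.06 from 143 ± 10 to 62.6 ± 3.9 FPKM and the amino acid transporter gene SLC38A2 fell by 1.23 ± 0.16. TGF-beta and BMP targets were lower for 9 of 11, by either count, with TSC22D1 at -0.56 ± 0.05 (camera adjusted p = 1.12e-06, and 0.03 with an estimated correlation). Immediate early genes were lower for 10 and higher for 0 of 28 (10 and 1 adjusted over the list alone). Among them MYC changed by -1.12 ± 0.06, the ERK phosphatase gene DUSP5 by -0.90 ± 0.07 and KLF6 by -0.71 ± 0.06 (camera adjusted p = 0.011, and adjusted p = 0.962 with an estimated correlation). That call was lost without DMSO heat shock library 3 (0.17) or ML-792 heat shock library 1 (0.292) or 3 (0.0816), and with fry (0.0808).

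limma called 4083 genes between ML-792 and DMSO under heat shock, 2241 higher and 1842 lower, with 26 at 2-fold or more (7 higher, 19 lower). The count was 2180 with the trend on GC content and length removed, and fell to 255 when the 6 heat shocked libraries were fitted alone, to 1629 without DMSO library 2 and to 2317 without ML-792 library 2. At 2-fold or more it was 10 and 15 without these libraries and 51 without ML-792 library 3. Of all calls 54.9% were higher, 37.1% with median-of-ratios scaling and 32.8% with equal totals. Of the 124 genes higher with ML-792 at 3.5 h without heat shock, 52 were also higher with it (22.8 for independent lists) and 16 were lower, and of 23 lower genes 15 were also lower (3.48 for independent lists). Over all genes, which are not independent replicates, the ML-792 changes without and with heat shock had a Pearson correlation of 0.07. The changes with heat shock had a Spearman correlation of 0.70 with GC content, against -0.14 without it. The value of 0.07 was not computed with that trend removed, so it cannot tell a different drug response from the trend.

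Whether ML-792 altered the heat response itself was tested as an interaction. The heat response of RGS2, a regulator of G protein signalling, was smaller under ML-792 by a difference of -1.47 ± 0.10 (adjusted p = 2.1e-05). Its level went from 12.8 ± 0.27 to 65.6 ± 5.4 FPKM in DMSO and from 20.5 ± 1.9 to 36.3 ± 0.98 FPKM in ML-792. DUSP5 differed by -1.19 ± 0.10, TRIB1 by -1.18 ± 0.09, MYC by -1.01 ± 0.08 and KLF6 by -0.85 ± 0.08. TRIB1 went from 93.1 ± 1.9 to 143 ± 10 FPKM in DMSO and from 93.2 ± 2.1 to 62.6 ± 3.9 FPKM in ML-792. The heat response of UBE2B was larger under ML-792 (0.75 ± 0.11). For HSPA6 the interaction (0.99 ± 0.16, adjusted p = 0.0097) only restates the difference between the heat shocked groups, since it stood near 0 without heat shock in both treatments and a ratio of heat responses is not determined. In the chaperone list 1 gene (HSPA6) was higher and 1 lower of 27, by either count, with no call in camera (adjusted p = 0.473). TGF-beta and BMP targets had a lower response for 4 of 11 (7 lower and 1 higher adjusted over the list alone), with ID2 at -1.11 ± 0.10 (camera adjusted p = 0.000134, and adjusted p = 0.0893 with an estimated correlation). Immediate early genes were lower for 7 of 28 (11 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0013, and adjusted p = 0.96 with an estimated correlation), a call lost without ML-792 heat shock library 1 (0.0571) and with fry (0.179). The G2 and mitosis list had a lower response (3 of 30 lower, or 10 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.0183, and adjusted p = 0.96 with an estimated correlation), and adjusted p = 0.505 with the trend on GC content and length removed and 0.107 with fry.

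limma called 781 interactions, 302 higher and 479 lower, with 18 at 2-fold or more (4 higher, 14 lower). The count was 267 with the trend on GC content and length removed, 247 with equal totals, 211 with no filter and 2194 without 2 doubtful libraries (DMSO heat shock 3 and ML-792 heat shock 2). The interactions had a Spearman correlation of 0.71 with GC content across genes, and GC content and length explained 43.1% of their variance. The calls of SNHG9 (0.93 ± 0.24), SNAPC5 (0.73 ± 0.13) and NDUFC2 (-1.94 ± 0.41), also named by the fixed rule, were lost without several libraries (highest adjusted p = 0.113, 0.0603 and 0.0879). The count was 79 and 1887 without DMSO heat shock libraries 2 and 3, 507 and 2520 without ML-792 heat shock libraries 2 and 3. It was 77, 89 and 102 without DMSO libraries 1, 2 and 3 of no heat shock, and 87, 91 and 107 without the ML-792 libraries 1, 2 and 3 of no heat shock. At 2-fold or more it was 29, 11 and 28 without DMSO heat shock libraries 1, 2 and 3, and 60 without ML-792 heat shock library 3. Of all calls 38.7% were higher, 19.8% with median-of-ratios scaling and 15.0% with equal totals.

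Camera called 97 of 263 list tests, and 12 of these also passed with an estimated correlation. They were ZNF-named genes and p53 targets in HCT116 at 16 h, ribosome biogenesis in COLO205, and TGF-beta and BMP targets, cholesterol synthesis, hypoxia response and interferon response in MDAMB231. The other calls were cholesterol synthesis, TGF-beta and BMP targets and hypoxia response between MDAMB231 and HCT116, TGF-beta and BMP targets for ML-792 under heat shock, and p53 targets between 16 h and 3.5 h. The median, mean and camera direction of a list differed in sign in 48 of the 263 tests, 0 of them called.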

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

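The reassignment of labels and the test of the heat shocked libraries alone with the trend removed were planned before their results were seen, and the other tests in this part were chosen after. Interaction tests gave 2765 called genes between COLO205 and HCT116, 1534 between MDAMB231 and HCT116, 3702 between MDAMB231 and COLO205, 4423 in the joint test of 3 lines, 781 for heat shock by ML-792 and 299 between 16 h and 3.5 h. Among genes with a mean above the median, the largest differences between COLO205 and HCT116 were those of ENTPD8 (5.50), NSMF (4.16), ADIRF (4.13), PLIN2 (3.01), EREG (-1.52), ASMTL (-1.43), PRSS1 (-1.36) and ODC1 (-1.34). Between MDAMB231 and HCT116 they were IL11 (2.52), TNFAIP2 (1.94), GDF15 (1.89), ID3 (1.87), DHRS2 (-2.64), G0S2 (-1.42), PLAT (-1.36) and ASMTL (-1.26). Between MDAMB231 and COLO205 they were GDF15 (2.91), MLXIPL (2.42), TNFAIP2 (2.28), AREG (1.92), ENTPD8 (-5.54), NSMF (-4.30), ADIRF (-4.10) and H19 (-2.83). For heat shock by ML-792 they were HSPA6 (0.99, with levels near 0 without heat shock), SNHG9 (0.93), UBE2B (0.75), SNAPC5 (0.73), NDUFC2 (-1.94), RGS2 (-1.47), DUSP5 (-1.19) and TRIB1 (-1.18). Between 16 h and 3.5 h they were DHRS2 (2.11), ASMTL (1.5), SUMO3 (0.92), ODC1 (0.91), ITGB4 (-0.99), CPA4 (-0.95), ADAM19 (-0.92) and HAS3 (-0.80).

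The calls were counted again after labels were reassigned among the libraries of each comparison. For comparisons of 2 groups there are 10 splits, too few for a share under 0.05. There the real split called 2101 genes in HCT116 at 16 h (highest other split 10), 5279 in COLO205 (2), 2403 in MDAMB231 (1), and 147 in HCT116 at 3.5 h (3). It called 6033 for heat shock in DMSO (1) and 7517 for heat shock in ML-792 (0), and in each case 1 of 10 splits, the real one, called as many. For ML-792 with heat shock the real split called 4083 genes and the highest other 806, so other splits of those 6 libraries also carry structure. With 82 splits, 1 of 82 called as many in each interaction, with highest others of 0 (COLO205 and HCT116), 21 (MDAMB231 and HCT116), 1 (MDAMB231 and COLO205), 2 (heat shock by ML-792) and 4 (16 h and 3.5 h). For the joint test of 3 lines 1 of 100 did so (highest other 1), as for the 175 higher and 117 lower shared genes (highest other 0 for both). In these interaction, joint and shared tests every other split exchanged 1 ML-792 library with 1 DMSO library in each line, time or heat condition. Such splits mix treated and vehicle libraries, so any effect of ML-792 widens the spread within groups and lowers the calls. The shares therefore cannot tell an interaction or a shared response from an effect of ML-792 alone.

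The breadth of the heat shock response (6033 genes in DMSO) was set against 3 other explanations. With the trend on GC content and length removed 6355 genes were called, so the number did not shrink without it. The trend explained 5.95% of the variance of the changes in DMSO. The count alone does not exclude that the trend made some of the calls, since removing it can also narrow the spread within groups. Under other scalings at least 6041 were called. A similar count does not exclude scaling, since a shift of all genes between the groups also makes calls, in either direction. The direction of the calls does depend on scaling, with 22.2% higher under equal totals against 58.4%, so the excess of higher genes could come from the scale of the values. A library batch cannot be told apart, since 0 libraries without heat shock have codes in the series of the heat shocked ones.

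The breadth of the ML-792 effect with heat shock (4083 genes) may owe much to the spread taken from the more even libraries without heat shock. In turn, the calls for ML-792 without heat shock (147 genes) may be lowered by the wider spread of the heat shocked libraries. The 6 heat shocked libraries alone called 255 genes, and 267 with the trend on GC content and length removed. In the fit of all 12 libraries removing that trend left 2180 genes, and it explained 42.0% of the variance of the changes, so how much of the breadth it accounts for is left open. The falls of RGS2, DUSP5 and TRIB1 in the interaction were -1.27, -1.30 and -1.25 with the trend removed, and their highest adjusted p over the 12 libraries left out in turn was 0.000437. Neither the trend nor a single library therefore accounts for these 3 genes.

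The rise of ZNF-named genes could reflect their GC content, whose median is 43.3% against 48.8% for all genes tested. With the trend on GC content and length removed, camera gave adjusted p = 9.27e-08 in HCT116 (9.13e-11 with the trend) and 4.25e-05 in MDAMB231 (4.75e-05), and the medians were 0.06 and 0.07. In COLO205 it gave adjusted p = 0.129 (0.0102 with the trend), and the median went from 0.05 to 0.02, so in that line the rise is not separated from GC content. With an estimated correlation only the HCT116 call held (adjusted p = 0.0264), and MDAMB231 and COLO205 gave 0.121 and 0.374.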

How the results depend on the processing

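The scalings, the removal of the trend on GC content and length and the removal of 2 doubtful libraries were chosen after the data were seen. Named genes gave 7125 results with the same call under an alternative, 270 weaker, 59 stronger and 0 reversed. A gene called in neither setting counts as the same, and most named genes were picked for large changes or small p-values in these data. The same call held in every alternative for 12 of 24 named genes for ML-792 with heat shock and 10 of 16 for heat shock by ML-792. It did so for 18 of 40 between times and 19 of 30 at 3.5 h, but for 36 of 36 and 28 of 28 for heat shock in DMSO and in ML-792. List tests gave 4786 the same, 241 weaker, 141 stronger and 2 reversed, and 93 counts moved by more than 1.5 times while 411 did not. For moved counts the cause was not tested. Array weights did not converge, and other size factors, a Wald test on counts and voom were not run, as the values are not counts.

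With an adjusted p under 0.01 the calls were 1055 in HCT116 at 16 h, 1408 in MDAMB231, 1429 between COLO205 and HCT116, 758 between MDAMB231 and HCT116, 2182 between MDAMB231 and COLO205, and 2533 in the joint test. They were 85 at 3.5 h, 1418 for ML-792 with heat shock (15 at 2-fold), 54 for heat shock by ML-792 (9 at 2-fold) and 96 between times. Of shared genes 84 were higher and 52 lower.

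In fits of only the groups compared the calls were 1316 in HCT116 at 16 h, 728 at 3.5 h and 255 for ML-792 with heat shock (11 at 2-fold), and 115 shared genes were higher. With the trend removed they were 260 at 3.5 h, 2180 for ML-792 with heat shock (10 at 2-fold), 267 for heat shock by ML-792 (10 at 2-fold), 781 between times, and 271 shared higher and 203 shared lower. Heat shock by ML-792 gave 247 with equal totals, 211 with no filter and 2194 without both doubtful libraries, and with equal totals 122 shared genes were higher and 184 lower.

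The number of genes at 2-fold or more followed the pseudocount. With pseudocount 0.1 and with pseudocount 5 it was 57 and 11 in HCT116 at 16 h, 262 and 44 in COLO205, 106 and 16 in MDAMB231, 265 and 39 between COLO205 and HCT116, 111 and 18 between MDAMB231 and HCT116, 313 and 46 between MDAMB231 and COLO205, and 9 and 0 at 3.5 h. It was 649 and 163 for heat shock in DMSO, 839 and 171 in ML-792, 49 and 11 for ML-792 with heat shock, 42 and 9 for heat shock by ML-792, and 14 and 2 between times.

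With 1 library left out the calls ranged from 1180 to 2822 in HCT116 at 16 h, from 83 to 93 at 3.5 h, from 1629 to 5011 for ML-792 with heat shock (10 to 51 at 2-fold), from 77 to 2520 for heat shock by ML-792 (11 to 60 at 2-fold) and from 156 to 808 between times. The lowest came without ML-792 library 3, ML-792 library 1, DMSO heat shock library 2, DMSO library 1 of no heat shock and 16 h ML-792 library 2, in that order. Shared genes ranged from 128 to 202 higher and from 80 to 175 lower.

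With fry 16 of the list results were weaker, among them all 4 lists called at 3.5 h (adjusted p from 0.0719 to 0.328), and 44 were stronger. The 2 list results counted as reversed were the SUMO pathway under fry after heat shock, higher with adjusted p = 0.000208 in DMSO and 0.000350 in ML-792, where camera gave the direction lower without a call. Fry tests against no change and camera against the other genes, whose median change was above 0 (0.05 in DMSO and 0.10 in ML-792). A list can therefore lie above 0 and below the other genes, and both signs can hold.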

Other observations

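The tests of neighbours in MDAMB231 and HCT116 and of ZNF-named genes among shared genes were planned before their results were seen, and the test of neighbours in COLO205 was changed after. ENTPD8, NSMF and PNPLA7 follow each other in RefSeq order, and in COLO205 they rose by 5.66, 4.15 and 3.12. Their neighbours NOXA1 and EXD3 changed by 0.89 ± 0.12 and 0.72 ± 0.13 (SE, n = 3 per group) and NRARP by 2.13 ± 0.28, with uneven ML-792 libraries (9.14 ± 6.30 FPKM, mean ± SD), and MRPL41 and DPH7, on the far side, by 0.19 and -0.07. In HCT116 ENTPD8, NSMF and PNPLA7 changed by 0.15, -0.01 and -0.02, and in MDAMB231 by 0.12, -0.15 and 0.04. Whether genes that rise lie side by side elsewhere was tested with 10000 shuffles. Of 82 genes that rose at least 2-fold in COLO205, 66 could be placed in order. The 63 apart from these 3 formed 4 adjacent pairs against a mean of 0.227 in shuffles (one-sided permutation p = 2e-04), more than random placement gave. The pairs were ATP11A and MCF2L, RNF103 and RMND5A, FAM53A and SLBP, and PLXNB3 and SRPK3. The shuffles drew risers from all placed genes without regard to GC content or level. A likeness of neighbours in these can therefore not be told from a local response. In HCT116 the 18 of 23 genes that could be placed formed 1 pair, GRHL1 and KLF11 (permutation p = 0.019), and in MDAMB231 29 of 33 formed 0 pairs (permutation p = 1).

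Of the 175 genes higher in all 3 lines 18 were ZNF-named against 5.28 expected, an odds ratio of 3.80 (95% interval 2.17 to 6.28; Fisher's exact test across genes p = 5.81e-06). This largely restates the excess of higher ZNF-named genes in each line, it was not repeated with the trend on GC content removed (which ended the COLO205 call, adjusted p = 0.129), and genes are not independent replicates. Among them were ZNF84 (0.76, 0.75 and 0.37 in HCT116, COLO205 and MDAMB231), ZNF432 (0.38, 0.73 and 0.74) and ZNF45 (0.43, 0.41 and 0.70).

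Across genes the ML-792 change had a Spearman correlation with GC content of -0.46 in HCT116 at 16 h, -0.26 in COLO205, 0.01 in MDAMB231, 0.70 in HCT116 with heat shock and 0.71 in the interaction with heat shock. Slopes per library against GC content ran from -0.10 to 0.10 log2 per 10% at 16 h and from -0.10 to 0.24 in the heat shocked libraries, where ML-792 library 2 had the steepest slope. Against transcript length the steepest slope of all libraries was that of DMSO heat shock library 3 (-0.13 log2 per doubling of length). Within groups, PC1 held 38.0% of the variance at 16 h and 44.5% at 3.5 h. Its absolute Spearman correlation across genes was 0.86 and 0.65 with GC content, and 0.30 and 0.54 with transcript length.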
